A study of Saccharomyces pastorianus with 12 samples.

How the data were processed

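The series held 12 samples of lager brewing yeast (Saccharomyces pastorianus, a hybrid yeast with an S. cerevisiae parent) taken during a production-scale lager fermentation, with total RNA as the labelled material and 1 array per sample. The sampling times were 0, 1, 24, 48, 72, 96, 120, 144, 168, 192, 240 and 264 h, per the labels. The deposited values were linear probe intensities, given as whole numbers for 6084 probes per array. The scanner, the background correction and any scaling by the authors were not given in the sources used here. No background signal or detection call came with the values, so the signal over background of a probe was unknown. The deposited intensities were not on a common scale. Array medians ran from 762 at 168 h to 10142 at 96 h, and the ratio of the 95th to the 5th percentile ran from 4.61 at 240 h to 34.4 at 1 h. The 168 h array held 3 intensities of 0, which were treated as missing.

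Probes were named through the platform annotation kept with the series. Of the 6084 probes, 5523 had 1 gene symbol, 561 had none and 0 had several. The 32 symbols with several probes were averaged on the log2 scale, which left 6051 tested rows, namely 5490 named genes and 561 unnamed probes. The names are those of S. cerevisiae genes. Copies from the other parent of the hybrid were not resolved, and probes of near-identical genes (paired ribosomal protein genes, seripauperin genes, HXT6 and its neighbour) can share signal.

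Intensities were log2 transformed and each array was centred on its median over genes measured on all arrays, so a level is the log2 distance from the median gene of the same array. With 1 array per time there was no replicate. Neighbouring times were therefore pooled into 4 windows by their labelled times, before the data were examined: 0 and 1 h (2 arrays), 24 to 72 h (3 arrays), 96 to 144 h (3 arrays) and 168 to 264 h (4 arrays). Window comparisons came from limma 3.58.1 in R 4.3.3 (lmFit and eBayes on all 12 arrays, 8 residual and 7.96 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The spread within a window holds array noise and real change between its times, and all arrays may come from 1 fermentation, so p-values speak for these samples. A gene needed a value on at least 9 arrays. Change over the whole course was tested with limma's moderated F test of a natural cubic spline with 3 degrees of freedom in hours.

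The 40 gene lists fixed before the data were examined were tested against all other genes with limma's camera at an inter-gene correlation of 0.01, and again with the correlation estimated per list. Counts of list members were made over all tested genes and adjusted over the list alone. For 1 h against 0 h, with 1 array each, there was no replicate of either time, and no test that borrows the spread of the other windows was run. List medians were placed among the medians of 10000 random lists of the same size matched on mean level. Random-list comparisons describe these arrays and carry no replicate error.

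Genes were named by a rule fixed before the data were examined. It took the 8 largest changes each way past the threshold whose arrays did not overlap between windows, or the 5 largest each way as values that did not pass, together with past-threshold members of called lists and 35 fixed genes. It also took the 10 largest differences each way between 1 h and 0 h among brighter genes and the 10 smallest p of the spline. Because few genes passed, the 3 list members with the largest change in each called list were added after the values were seen.

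The fits were tested on simulated data with the fitted spread of 6048 genes, 200 of them changed. The simulated noise was independent for each gene and array. In the real arrays the estimated inter-gene correlation was 0.58 for ergosterol genes from 0 and 1 h to 24 to 72 h. The shares, false calls and list results below therefore do not speak for correlated genes. For 24 to 72 h against 0 and 1 h, 55% of genes changed by 2 log2 units and 99% of those changed by 4 were recovered, with 9 false calls. For 168 to 264 h against 24 to 72 h the shares were 71% and 100%, with 9 false calls, and for the spline 18% and 98%, with 8 false calls. A list shifted by 1 log2 unit was found with the preset correlation and missed with the estimated one in both window comparisons.

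Alternatives were the values as deposited without centring, quantile normalization, genes with values on all arrays, removal of the dimmest 25% of genes, a floor at the 5th percentile, other variance models, other windows and time scales, and leaving out each array. Normexp background correction with an offset of 50, equalised median absolute deviations and a rank correlation of list means with time were added after seeing the data. The number of arrays limits the precision. No genome was used, so no positions are given. Figures were drawn with matplotlib 3.10.9.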

Results

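Transcript levels of lager brewing yeast were measured at 12 times during a production-scale fermentation, from 0 to 264 h, with 1 array at each time and so no replicate check of any single time. The series followed gene expression over the fermentation. Array medians lay between 762 and 10142 intensity units. The 240 h array had the narrowest signal, with a standard deviation of 0.67 log2 units, and a median Spearman correlation across genes of 0.253 with the other arrays. The highest correlation of any pair was 0.842, between 120 and 168 h. Levels below are log2 distances from the median gene of the same array.

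**Figure D1:**
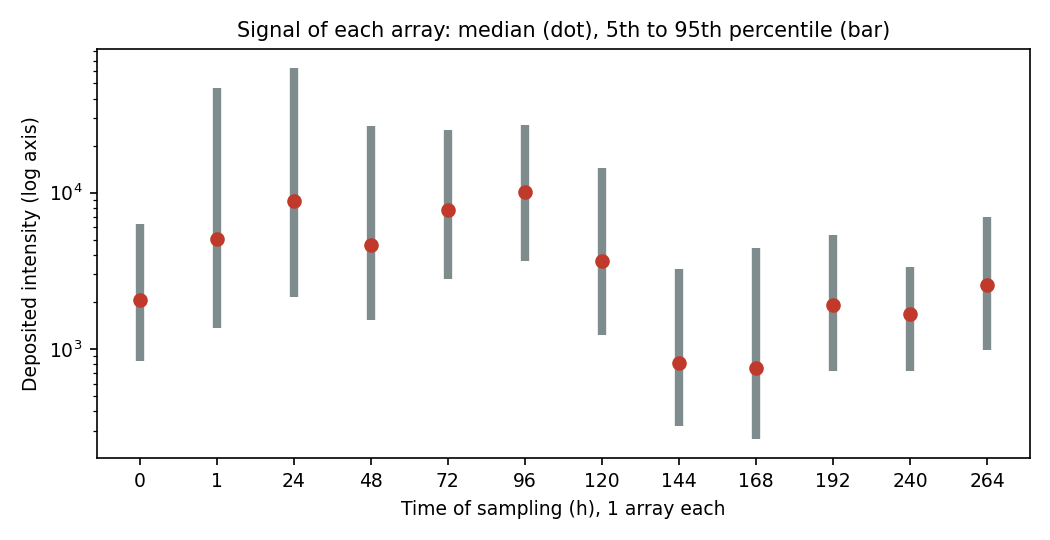
Deposited intensity of the 12 arrays on a log axis by time of sampling in h, with the median as a dot and the 5th to 95th percentile as a bar. Medians run from 762 to 10142, and the bars are widest at 1 h, where the percentile ratio is 34.4, and narrowest at 240 h, where it is 4.61.

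The array at 1 h differed from that at 0 h most in genes of protein synthesis, with 1 array each and no replicate check. Of 132 measured cytosolic ribosomal protein genes, 130 were higher at 1 h, with a median difference of 4.57 log2 units or 23.7-fold (5.29-fold after quantile normalization). Translation initiation and elongation factors had a median difference of 3.19, with 27 of 28 genes higher, and 1.40 after quantile normalization. Ribosome biogenesis genes had a median difference of 1.03, with 55 of 72 higher, and 0.64 after quantile normalization. Glycolysis and ethanol formation genes had a median of 2.31 (4.96-fold), with 20 of 21 higher, but of 0.47 (1.39-fold), with 15 of 21 higher, after quantile normalization. The heat shock and general stress list had a median of -0.80, with 15 of 33 genes higher, and of -1.04, with 9 higher, after quantile normalization.

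The 10 largest increases were 9 ribosomal protein genes and TMA19, a ribosome-associated protein. They ran from RPL1B at 40.3-fold to RPL11A at 63.5-fold. RPS2 was 57.4-fold and RPL5 53.8-fold higher. After quantile normalization the log2 differences were smaller, 4.02 for RPL11A against 5.99 median-centred, 4.35 for RPS2 against 5.84, 3.73 for RPL5 against 5.75 and 3.70 for RPL1B against 5.33. The largest decreases were in MXR2, a methionine sulfoxide reductase, at 24.3-fold. IZH2 was 17.9-fold lower, RPN4, the activator of proteasome genes, 14.1-fold, HSP26, a small heat shock protein, 13.8-fold, and OLE1, the fatty acid desaturase, 12.7-fold. The cell wall genes SPI1 and PST1 were 11.5- and 11.3-fold lower. CSM1, YBR090C and RCR1 were the other 3 of the 10 largest decreases, but their signals at 1 h were below the 5th percentile of that array (1361 units), where the background was unknown, so the sizes of their decreases are left out. OLE1 stood at 6.13 at 0 h, 2.46 at 1 h and 5.94 at 24 h.

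Against the central 95% of 10000 random lists matched on mean level, 7 of the 40 list medians lay above and 7 below, of which 6 and 4 did so after quantile normalization too. The 6 were ribosomal proteins, translation factors, ribosome biogenesis, glycolysis, purine and pyrimidine synthesis (median 1.09) and secretion and folding in the endoplasmic reticulum (0.76). The 4 were heat shock, glycogen and trehalose metabolism (-0.51), iron and copper uptake (-0.59) and seripauperin genes (-0.47). The proteasome list (1.10) lay above, and peroxisomal fatty acid oxidation (-0.83), fatty acid and phospholipid synthesis (-0.54) and hypoxic genes (-0.50) lay below, in median-centred values alone. As deposited, the median of all genes differed by 1.30 log2 units between these arrays, by 1.07 from 0 and 1 h to 24 to 72 h and by -2.11 from there to 168 to 264 h, and all changes here are relative to it. Over 4-fold differences numbered 578 genes higher and 251 lower of 6048, or 281 and 242 after quantile normalization. The Spearman correlation of the 2 arrays across genes was 0.399.

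**Figure D2:**
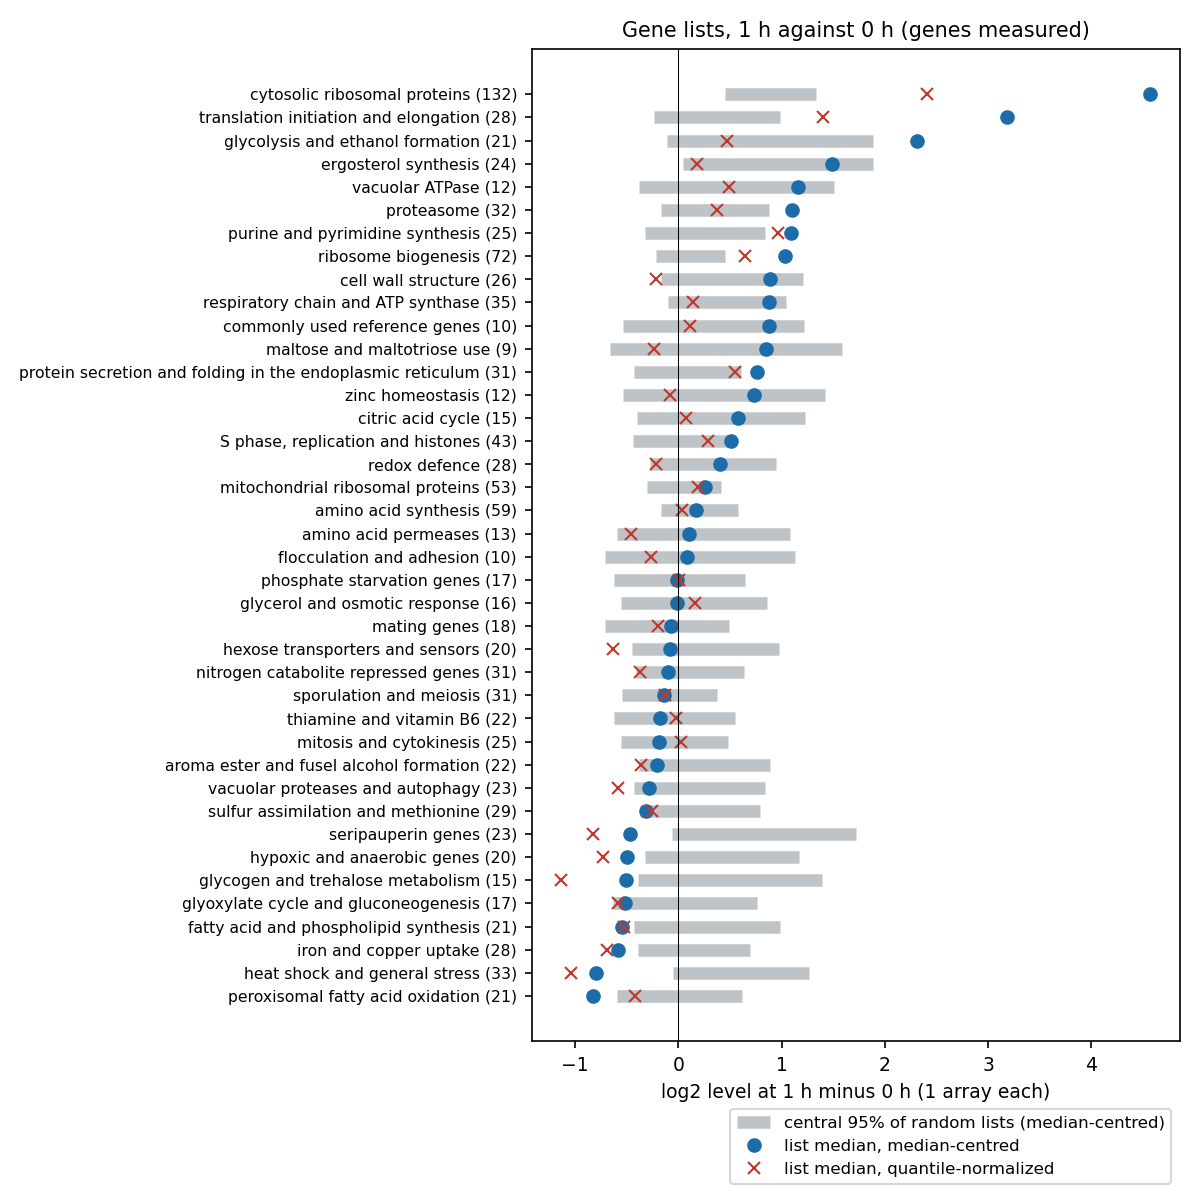
Median log2 level at 1 h minus 0 h (horizontal axis, 1 array each) of each of the 40 gene lists, as a dot for median-centred and a cross for quantile-normalized values, with the central 95% of matched random lists as a bar. The ribosomal protein list lies farthest right, at 4.57 median-centred and 2.40 quantile-normalized.

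From 0 and 1 h to 24, 48 and 72 h, sterol genes were higher as a group and hexose transporter genes lower. All 24 genes of ergosterol synthesis, the yeast's main sterol, were above their early mean, and the list rose by a mean of 1.71 log2 units (3.26-fold; list mean 1.76 ± 1.01, SD, n = 2, then 3.47 ± 0.38, n = 3; camera adjusted p = 3.18e-30, adjusted p = 0.172 with an estimated correlation). 15 of the 24 genes were higher adjusted over the list alone, and 0 over all genes. Without the 0 h array the mean rise was 0.99 (adjusted p = 4.26e-06), and without the 1 h array 2.42. The hexose transporter and sensor list fell by a mean of 1.06, with 16 of 20 genes lower and 2 of them past the threshold adjusted over the list alone (adjusted p = 1.01e-07, adjusted p = 0.289 with an estimated correlation).

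Among the sterol genes, ERG5 was at 2.80 ± 0.23 early and 5.26 ± 0.23 at 24 to 72 h, 5.52-fold higher, ERG3, a sterol desaturase, 5.51-fold, ERG1, the squalene epoxidase, 4.62-fold, and ERG11, the lanosterol demethylase, 3.68-fold. CYB5, a cytochrome that serves sterol enzymes, was 6.12-fold higher. Among the transporters, HXT1 was at 3.82 ± 0.99 early and 1.30 ± 0.30 later, 5.74-fold lower, with HXT3 5.65-fold and HXT6 5.52-fold lower. Without the 0 h array the log2 changes of ERG3, ERG1, ERG11 and CYB5 were 1.40, 1.18, 0.71 and 1.64, against 2.46, 2.21, 1.88 and 2.61 with it. That of ERG11 was 3.05 without the 1 h array. None of these single genes passed over all genes in limma. They and the other example genes of called lists were chosen after their values were seen, unless fixed beforehand.

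Other lists past the same test were smaller in change. All 23 seripauperin genes, a family of near-identical cell wall protein genes, were higher by a mean of 0.86 (adjusted p = 1.13e-13, adjusted p = 0.289 with an estimated correlation). Of 29 genes of sulfur assimilation and methionine synthesis, 22 were higher (mean 0.53; adjusted p = 1.23e-05, adjusted p = 0.112 with an estimated correlation), 1 of them adjusted over the list alone. MET6, the methionine synthase, went from 0.60 ± 0.26 to 4.16 ± 0.66, the largest difference of the comparison at 11.8-fold (limma adjusted p = 0.199). SAM2 was 4.10-fold and CYS4 3.46-fold higher (CYS4 by 0.98 log2 units without the 0 h array, against 1.79 with it). MET3, MET10 and MET14 of the sulfate pathway were 1.37-, 1.85- and 1.53-fold higher, and the sulfite pump gene SSU1 1.84-fold. The log2 differences of MET3, MET10 and MET14, 0.46, 0.89 and 0.61, were 0.05, -0.07 and 0.31 without the 1 h array, and those of MET3 and MET10 0.86 and 1.84 without the 0 h array. MET14 had 0.32 after quantile normalization. The signal of MET10 at 1 h was below the 5th percentile of that array, where the background was unknown. Of 20 hypoxic and anaerobic genes 17 were higher (mean 0.63; adjusted p = 3.85e-05, adjusted p = 0.289 with an estimated correlation), among them TIR1 at 2.17-fold. HEM13 and DAN1 differed by 0.58 and 0.62 log2 units, but HEM13 by 0.33 without 48 h and DAN1 by 0.26 without 1 h and 0.98 without 0 h. The difference of OLE1, 1.58 log2 units, was 3.41 without the 0 h array and -0.25 without the 1 h array, so it had no stable direction. Without the 1 h array the hypoxic list (mean 0.45, adjusted p = 0.218) and the sulfur list (mean 0.51, adjusted p = 0.0549) no longer passed.

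Amino acid synthesis (38 of 59 genes higher, LEU1 3.08-fold), purine and pyrimidine synthesis (16 of 25, ADE17 2.95-fold), the respiratory chain (25 of 35, COX4 2.91-fold, CYC1 2.37-fold and COX5A 2.06-fold) and iron and copper uptake (20 of 28, FTR1 2.41-fold) also passed upward, with adjusted p from 0.00286 to 0.0155. With an estimated correlation these 4 lists had adjusted p from 0.518 to 0.654. Without the 0 h array the log2 differences of ADE17, COX4 and FTR1 were 1.01, 0.87 and 0.30, against 1.56, 1.54 and 1.27 with it, and that of FTR1 was 2.23 without the 1 h array. Glycogen and trehalose metabolism passed downward, with 13 of 15 genes lower, UGP1 2.45-fold, GSY2 2.16-fold (log2 difference -0.13 without 0 h and -2.09 without 1 h, against -1.11) and TPS1 2.07-fold (adjusted p = 0.0155, adjusted p = 0.595 with an estimated correlation). Adjusted over the list alone, 0 members of these 5 lists, of the seripauperin list and of the hypoxic list passed. Without the 0 h array, adjusted p rose to 0.525 for amino acid synthesis, 0.858 for purine and pyrimidine synthesis, 0.874 for the respiratory chain and 0.858 for glycogen and trehalose. Their mean changes, 0.24, 0.32, 0.28 and -0.56 with all arrays, were then 0.01, -0.26, -0.04 and -0.27, and without the 1 h array 0.48, 0.91, 0.60 and -0.86. Without 72 h the change was 0.56 for purine and pyrimidine synthesis and 0.42 for the respiratory chain. Purine and pyrimidine synthesis also failed without 24 h (0.139), the respiratory chain without 48 h (0.352), and glycogen and trehalose without 48 h (0.0918) or 72 h (0.0505). The iron and copper list failed without 1 h (0.963) or 72 h (0.106) and after quantile normalization (0.0968). Its mean change of 0.29 was 0.58 without 0 h and -0.01 without 1 h. The remaining 30 lists did not pass, with adjusted p from 0.0711 to 0.963. After quantile normalization 12 lists passed, 9 of them among these 10. The 3 others were heat shock (downward, adjusted p = 0.00885, against 0.111 median-centred), glycolysis (upward, 0.00185, against 0.450) and ribosomal proteins (upward, 4.35e-05, against 0.952).

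Fixed genes of sugar use and aroma showed smaller differences that did not pass. MAL32, a maltase, was 2.26-fold higher (log2 difference 0.13 without 0 h and 2.23 without 1 h), and HXT5 was 2.10-fold lower (-0.61 without 1 h). Most of the other differences depended on which early array was used. Those of PDC1 (-0.03), ADH1 (-0.16), ADH2 (-0.72), ACT1 (-0.18), MAL11 (-0.29) and MAL12 (-0.51) were 2.24, 1.05, 0.45, 1.41, 0.93 and 0.05 without the 1 h array and -2.30, -1.37, -1.89, -1.77, -1.52 and -1.07 without the 0 h array. MAL31, a maltose permease, differed by 0.33, and by -0.00 without 0 h, 0.66 without 1 h, -0.07 without 48 h and 0.60 without 72 h. In log2 units, with the range over single arrays left out, the ester and fusel alcohol genes ATF1, ATF2 and BAT2 differed by 0.14 (-0.19 to 0.34), 0.89 (0.17 to 1.61) and -0.04 (-0.30 to 0.22). HSP12, HSP26 and HSP104 differed by 0.40 (-0.48 to 1.28), -0.31 (-2.20 to 1.58) and -0.49 (-0.93 to -0.12), GAP1 by -0.15 (-0.46 to 0.16) and ICL1 by 0.07 (-0.15 to 0.29). FLO1 was 1.35-fold lower (-0.18 without 24 h, against -0.43). After quantile normalization the differences of ADH1, PDC1, GAP1 and ACT1 changed sign, and those of ADH2, ATF1, HSP12, HSP26, MAL11 and MAL12 were -0.36, 0.04, 0.12, -0.59, -0.08 and -0.27. YDL086W was 5.54-fold higher, and YLR162W 7.58-fold and FRA1 5.29-fold lower (log2 differences of -1.31 and -1.24 without 0 h, against -2.92 and -2.40 with it). YLR162W differed by -4.53 without 1 h, and FRA1 by -1.49 without 24 h. The signals of FRA1 at 24 h and of ATF2 at 0 h were below the 5th percentile of their arrays, where the background was unknown.

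In limma, 0 of 6051 genes passed, with 97 higher and 74 lower at an unadjusted p under 0.05, against 302.6 expected by chance, and 0 also passed in the linear model without moderation. The windows did not overlap for 399 genes that were higher later and 430 that were lower, together 13.7% against 20% by chance. The ribosomal protein list stood at 0.52 at 0 h and 4.89 at 1 h, so its change to 24 to 72 h was -2.26 without the 0 h array and 2.11 without the 1 h array. With both it was -0.08 (adjusted p = 0.952), and 0.34 after quantile normalization (adjusted p = 4.35e-05). Translation factors (mean -0.25) likewise went to -1.59 and 1.08, and glycolysis (0.14) to -0.93 and 1.20, without 0 h and without 1 h.

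From 24, 48 and 72 h to 168, 192, 240 and 264 h, genes of protein synthesis, sterol synthesis and glycolysis were lower as groups. Of 132 ribosomal protein genes 128 were lower, and the list fell by a mean of 2.16 log2 units (list mean 2.63 ± 1.10, n = 3, then 0.47 ± 0.50, n = 4; camera adjusted p = 3.34e-41, adjusted p = 0.438 with an estimated correlation). 106 of its members were lower and 1 higher adjusted over the list alone, and 0 passed over all genes. All 24 ergosterol genes were lower, and the list fell by a mean of 2.40 (3.47 ± 0.38, then 1.07 ± 0.93; adjusted p = 4.90e-26, adjusted p = 0.340 with an estimated correlation), with 23 lower adjusted over the list alone and 3 over all genes. Of 21 glycolysis and ethanol formation genes 19 were lower, and the list fell by a mean of 1.80 (3.23 ± 0.61, then 1.43 ± 0.87; adjusted p = 1.46e-11, adjusted p = 0.438 with an estimated correlation), with 15 lower adjusted over the list alone and 0 over all genes. After quantile normalization all 3 lists still passed, with list medians of -1.78 against -2.23 for ribosomal proteins, -1.99 against -2.60 for ergosterol and -1.03 against -2.23 for glycolysis.

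The 5 genes that passed over all genes all fell. MET6 fell 11.5-fold (log2 change -3.53, SE 0.52; limma adjusted p = 0.0289). BIO2, the biotin synthase, fell 6.98-fold (-2.80, SE 0.45; adjusted p = 0.0325). The sterol genes ERG13 (the synthase of HMG-CoA), HMG1 (its reductase) and ERG7 (the lanosterol synthase) fell 8.55-, 6.88- and 6.30-fold, each with an adjusted p of 0.0413. In all 5, every late array lay below every array from 24 to 72 h. MET6 lost its call without 24, 48, 120, 192, 240 or 264 h, BIO2 and ERG7 also without 96 h, and ERG13 and HMG1 also without 72 or 96 h, with adjusted p up to 0.304. ERG11, ERG5, ERG1 and ERG3 were 11.8-, 10.6-, 9.35- and 8.07-fold lower without passing (adjusted p from 0.106 to 0.107). After quantile normalization the 5 genes passed too (ERG13 with a log2 change of -1.97, against -3.10 median-centred), and so did ERG11 (adjusted p = 0.0482) and ERG1 (0.0475).

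In the ribosomal protein and glycolysis lists the members with the largest differences did not pass over all genes in median-centred values. RPS6B differed by -3.58 log2 units, and RPL15A was 9.57-fold and RPS6A 9.48-fold lower. Of the glycolytic genes, FBA1, the aldolase, was 11.6-fold, TDH3 6.93-fold, PDC1, the pyruvate decarboxylase, 6.76-fold and ADH1 3.44-fold lower. After quantile normalization RPS6B (adjusted p = 0.0359), RPL15A (0.0358), RPS6A (0.0306) and FBA1 (0.0352) passed, while TDH3 (log2 change -1.37, against -2.79 median-centred), PDC1 and ADH1 (-0.99, against -1.78) did not. ACT1, the actin gene often taken as a constant reference, was 3.93-fold lower without passing (limma adjusted p = 0.177). After quantile normalization its log2 change was -1.41, against -1.97 median-centred, and did not pass either (adjusted p = 0.0906).

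The hexose transporter list was the 1 list to pass upward in median-centred values. Its mean rose by 0.74, from 0.12 ± 0.07 to 0.86 ± 0.72, with 17 of 20 genes higher and 0 past adjusted over the list alone (adjusted p = 0.00286, adjusted p = 0.511 with an estimated correlation). Without the 168 h array its mean change was 0.41 (adjusted p = 0.0906). HXT1, HXT6 and HXT3 were 3.50-, 3.23- and 3.17-fold higher without passing (1.20, 0.87 and 1.00 log2 units without 168 h, against 1.81, 1.69 and 1.67), and HXT1 passed after quantile normalization (log2 change 2.94, adjusted p = 0.0306). The heat shock list had a mean of 0.30 and did not pass (adjusted p = 0.299), but passed upward after quantile normalization (adjusted p = 0.00232). Its members HSP30, HSP26 and HSP12 were 6.26-, 3.07- and 2.16-fold higher, but HSP26 and HSP12 by 0.91 and 0.70 log2 units without the 168 h array, against 1.62 and 1.11 with it, and by 2.47 and 1.75 after quantile normalization. HSP104 differed by 0.01, and changed sign without 48, 72, 168 or 192 h.

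11 more lists passed downward. Translation factors (25 of 28 lower, 6 adjusted over the list alone, mean -1.18), purine and pyrimidine synthesis (24 of 25, 4, -0.97), the respiratory chain (30 of 35, 1, -0.82) and amino acid synthesis (45 of 59, 8, -0.58) had adjusted p from 1.36e-07 to 2.75e-06, and adjusted p from 0.340 to 0.438 with an estimated correlation. Named members were HYP2 at 8.46-fold, IMD4 at 4.76-fold, CYC1 at 3.39-fold (log2 change -1.02 after quantile normalization, against -1.76), COX4 and COX5A at log2 changes of -2.32 and -2.07, and ILV5 and BAT1 of branched-chain amino acid synthesis at 5.69- and 5.36-fold. Of these, COX4, ILV5 and BAT1 passed over all genes after quantile normalization (adjusted p from 0.0475 to 0.0482). The signal of COX5A at 240 h was below the 5th percentile of that array, where the background was unknown. The vacuolar ATPase (10 of 12 lower), seripauperin (21 of 23), cell wall (17 of 26), ribosome biogenesis (51 of 72), proteasome (25 of 32), sulfur (18 of 29) and hypoxic (15 of 20) lists had adjusted p from 0.00284 to 0.0472, and from 0.438 to 0.623 with an estimated correlation. Adjusted over the list alone, 0 vacuolar ATPase, 0 seripauperin, 2 cell wall, 0 ribosome biogenesis, 0 proteasome, 5 sulfur and 1 hypoxic genes were lower. SAM2 and CYS4 were 6.85- and 5.45-fold lower (SAM2 by -1.78 log2 units after quantile normalization, against -2.78), while MET3 was 1.02-fold lower (higher by 0.17 log2 units after quantile normalization and by 0.15, 0.21 and 0.16 without 48, 168 and 264 h) and MET10 1.53-fold higher. ANB1, a hypoxic translation factor, was 8.57-fold lower, TIR1 3.35-fold and OLE1 2.28-fold. The levels of ANB1 were close to those of HYP2 at 1 h (5.91 and 6.12) and 240 h (0.78 and 0.91), and shared signal between their probes was not excluded. After quantile normalization ANB1 differed by -2.06 log2 units (adjusted p = 0.0482), TIR1 by -0.03 (against -1.74 median-centred) and OLE1 by 0.24. Without the 240 h array the median-centred differences of TIR1 and OLE1 were -1.11 and -0.39 log2 units, and without 168 h that of OLE1 was -2.15, against -1.19.

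Of the 15 lists, 9 also passed after quantile normalization. The 6 that did not were the last 7 named without the vacuolar ATPase, namely ribosome biogenesis, seripauperin and proteasome genes (each with an adjusted p of 0.107), sulfur genes (0.148), cell wall genes (0.229) and hypoxic genes (0.706). The calls of the same 6 lists also depended on single arrays. Ribosome biogenesis failed without 24 h (0.223) or 168 h (0.110), seripauperin genes without 72 h (0.0572) or 240 h (0.100), and cell wall genes without 240 h (0.0623). The hypoxic list failed without 0 h or 1 h (0.0736), 48 h (0.156), 72 h (0.0696), 240 h (0.131) or 264 h (0.129), and the sulfur list without 0 h or 1 h (0.0736), 48 h (0.156), 240 h (0.0623) or 264 h (0.104). The proteasome list failed without 0 h or 1 h (0.0558), 24 h (0.0972), 48 h (0.125), 240 h (0.108) or 264 h (0.235). Mean changes moved over 1.5 times without 24 h for ribosome biogenesis (-0.28 to -0.15), without 168 h or 240 h for seripauperin genes (-0.48 to -0.82 or -0.27), without 240 h for cell wall (-0.54 to -0.30) and hypoxic genes (-0.55 to -0.33), and without 72 h or 168 h for the proteasome (-0.35 to -0.53 or -0.55). The remaining 25 lists did not pass, with adjusted p from 0.0589 to 0.997.

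Maltose genes did not pass in median-centred values, and MAL32 passed after quantile normalization (adjusted p = 0.0475). Of those named here only MAL12 was higher, and it stayed near the median gene over the whole course (-1.01 to 0.82), while MAL32 reached 5.42. MAL32 was 6.99-fold lower. In log2 units MAL11 differed by -1.29 (-0.76 without 24 h), MAL31 by -1.24 (-0.58 after quantile normalization), MAL12 by 0.50 (0.24 without 240 h and 0.82 without 48 h) and ADH2 by -1.11 (-0.17 after quantile normalization). ATF1 differed by -0.64 (-0.30 without 24 h), ATF2 by -0.76 (-0.33 without 24 h and -1.34 without 72 h) and BAT2 by -0.39 (-0.20 without 72 h and -0.59 without 168 h). SSU1 differed by -0.63 (-0.17 without 240 h and -1.02 without 264 h), DAN1 by -0.65 (-0.28 without 240 h and -1.01 without 48 h) and FLO1 by -0.31 (-0.12 without 240 h and -0.82 without 168 h). The signals of ATF2 at 264 h and of SSU1 at 240 h were below the 5th percentile of their arrays, where the background was unknown. MET14 differed by -0.49 (-0.02 without 240 h, -0.83 without 168 h and -0.14 after quantile normalization), HEM13 by -0.38 (0.07 without 264 h, -0.73 without 192 h and -0.04 after quantile normalization) and GAP1 by -0.12 (0.03 without 48 h, -0.38 without 24 h and -0.19 after quantile normalization). HXT5, TPS1 and GSY2 differed by 0.48, 0.64 and 0.59, but by -0.09, -0.01 and 0.15 without the 168 h array and 0.99, 1.14 and 1.07 without the 240 h array. HXT5 and TPS1 had 0.90 and 1.33 after quantile normalization. ICL1 differed by 0.19 (-0.03 without 24 h and 0.41 without 72 h). The 5 largest increases that did not pass were SPG1, a stationary-phase gene, at 7.63-fold, YLR162W at 7.55-fold, HSP30 at 6.26-fold, NAT4 and an unnamed probe (171). The signals of NAT4 and probe 171 at 24, 48 and 72 h were below the 5th percentile of each array. The background was unknown there, so the sizes of their increases are left out. After quantile normalization SPG1 (log2 change 3.72, against 2.93 median-centred; adjusted p = 0.0306), YLR162W (3.87, against 2.92; 0.0306) and HSP30 (3.51, against 2.65; 0.0359) passed.

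**Figure D3:**
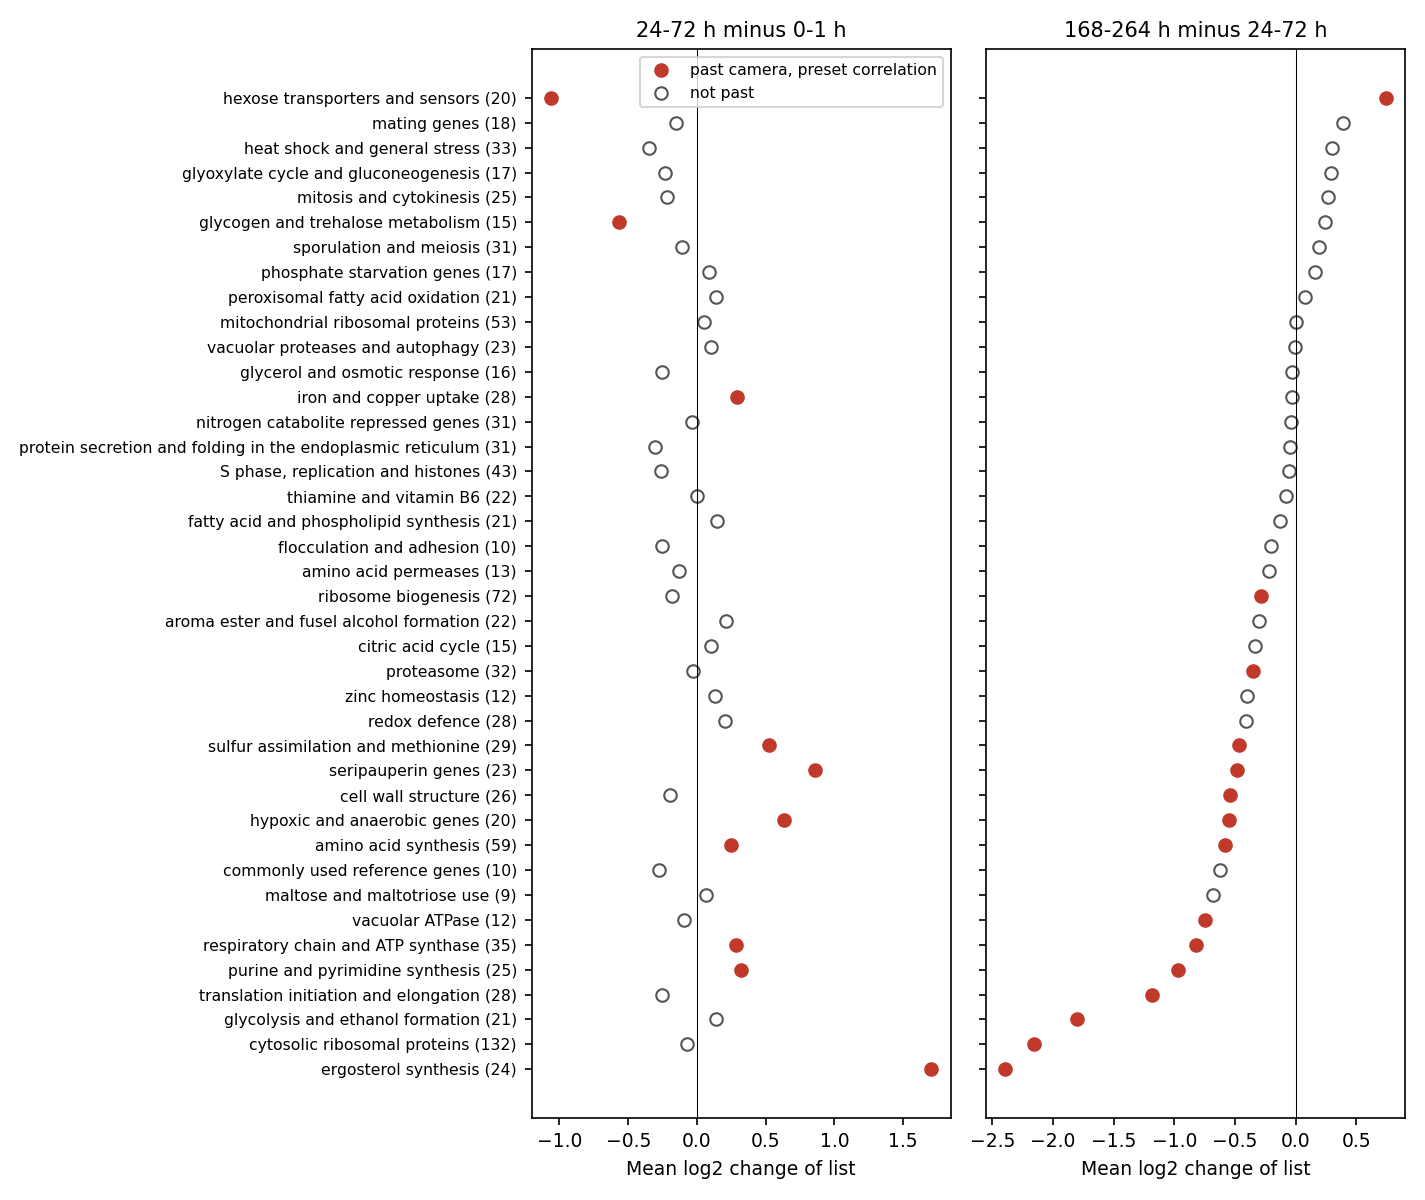
Mean log2 change of each of the 40 gene lists (horizontal axis) from 0-1 h to 24-72 h on the left and from 24-72 h to 168-264 h on the right, filled where the list passed camera with the preset correlation. Ergosterol synthesis lies at 1.71 on the left and -2.40 on the right, hexose transporters at -1.06 and 0.74, and ribosomal proteins at -0.08 and -2.16.

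At an unadjusted p under 0.05, 374 genes were higher and 525 lower, against 302.6 expected, and windows did not overlap for 12.5% of genes against 5.71% by chance. After quantile normalization 72 genes passed (11 higher, 61 lower) against 5 (0 higher, 5 lower) with median centring. The median-centred count of 5 went to 0 without any 1 of the arrays at 24, 48, 120, 192, 240 or 264 h, to 1 without 96 h, to 3 without 72 h, to 109 without 168 h and to 257 without 0 h or without 1 h.

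Over the whole course, 2 genes passed the spline test, a sterol desaturase gene and a copper metallothionein gene. ERG5 stood at 2.63 at 0 h and 2.96 at 1 h, 5.47 at 24 h, 4.47 at 168 h, 2.35 at 192 h and 0.03 at 240 h (adjusted p = 0.0221). CUP1-2 stood at 1.57 at 0 h, -0.02 at 72 h, 3.67 at 168 h and 0.72 at 264 h (adjusted p = 0.0221). The next 8 genes by p did not pass and held ERG11, HMG1, ERG1, ERG13, MET6 and SPG1, with IST3 and YJR029W (adjusted p from 0.0721 to 0.128).

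The list means followed different courses. Ribosomal proteins were highest at 1 h (4.89), then stood at 3.70 at 24 h, 1.51 at 72 h and 0.04 at 240 h. Ergosterol genes were highest at 24 h (3.75; after quantile normalization at 72 h, 3.20) and stood at 2.35 at 168 h and 0.92 at 192 h. Hexose transporters stood at 1.19 at 0 h, 0.04 at 24 h, -0.15 at 96 h and 1.87 at 168 h. In median-centred values MAL11 was highest at 1 h (2.96), MAL32 at 24 h (5.42), MAL31 at 48 h (3.07), and TPS1, HXT5, HSP12 and HSP26 at 168 h (4.38, 3.59, 3.33 and 5.24).

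**Figure D4:**
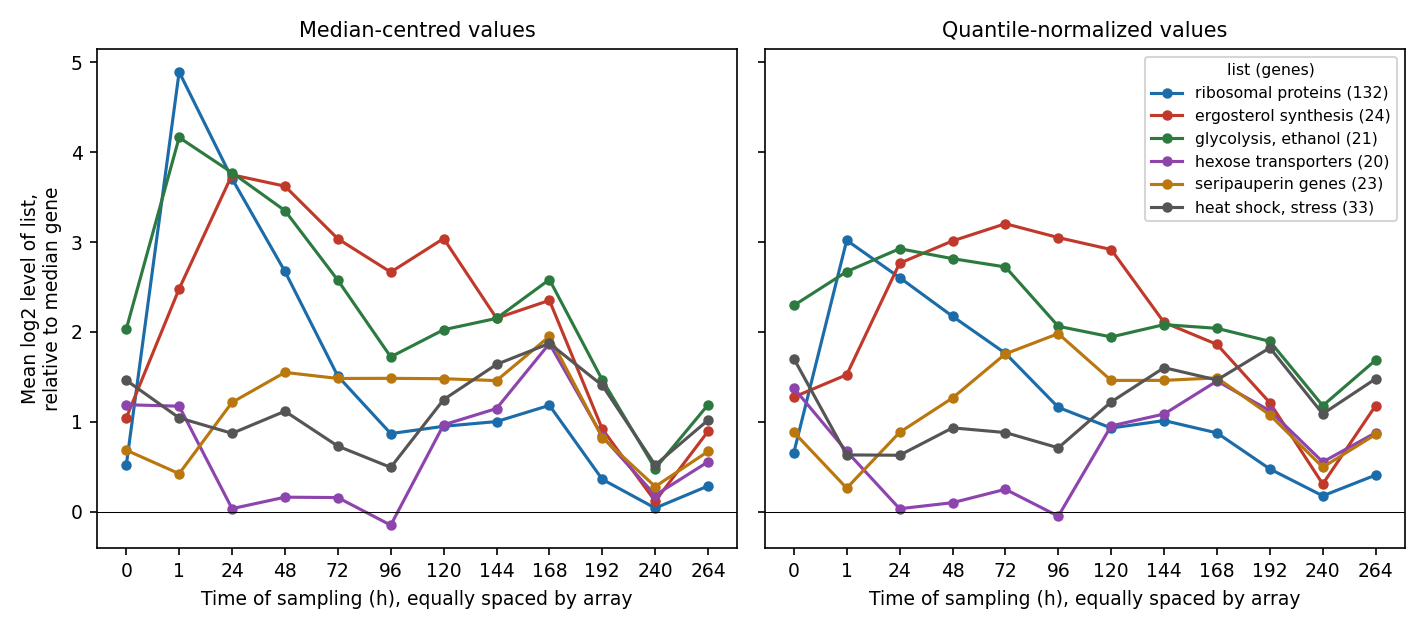
Mean log2 level of 6 gene lists relative to the median gene (vertical axis) at the 12 times in h, spaced equally by array, median-centred on the left and quantile-normalized on the right; each point is 1 array. Median-centred ribosomal proteins go from 0.52 at 0 h to 4.89 at 1 h and 0.04 at 240 h.

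The spline p was under 0.05 before adjustment for 16.1% of genes, against 5% expected by chance. The number of genes changing over the time course, 2 with median centring, became 68 after quantile normalization. With median centring it was 1113 without the 0 h array, 0 without any 1 of the arrays at 48, 72, 144, 192, 240 or 264 h, 1 without 96 h or 120 h, 3 without 24 h and 4 without 168 h.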

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

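Tests chosen only after the results were seen were normexp background correction, equalised median absolute deviations and the rank correlation of list means with hours. Of 2040 values of single genes under 25 alternatives, 1888 kept their side of the threshold, 101 newly passed and 51 no longer passed. Among the 1888, 84 changed sign without passing under either setting (24 sign changes as deposited, 6 after quantile normalization), and 0 values passed in the opposite direction. Of 1600 list values 1481 kept their side (101 with a changed sign), 30 newly passed (1 with a changed sign), 83 no longer passed (3 with a changed sign) and 6 passed in the opposite direction. Of 219 values of time-course genes 152 kept their side, 46 newly passed and 21 no longer passed.

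The cause was not tested where none is given. The count of genes changed between 24 to 72 h and 168 to 264 h, 5 with median centring, was 2125 as deposited (all lower, with the all-gene shift of -2.11 left in), 72 after quantile normalization, 62 with equal median absolute deviations, 216 with only the arrays compared, 316 with 192, 240 and 264 h against 24 and 48 h, and 390 with a linear trend from 24 to 264 h. It was 0 with eBayes trend and robust, 0 with no moderation and 0 with normexp. Without single arrays it ran from 0 to 257, the highest without 0 h or 1 h, where 0 and 1 h no longer add their spread to the residual. The count of genes changing over the time course, 2 in hours, was 5091 as deposited, 68 after quantile normalization, 53 with equal median absolute deviations, 272 with log2(hours + 1), 4 with normexp and 0 with eBayes trend and robust. It ran from 0 to 1113 without single arrays, the highest without 0 h. Genes changed between 0 and 1 h and 24 to 72 h stayed at 0 in every alternative run in limma or without moderation (97 higher and 74 lower at an unadjusted p under 0.05).

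With an estimated correlation, which widens the null of correlated genes, 0 of the 10 and 0 of the 15 lists passed in median-centred values. With it after quantile normalization, ergosterol and sulfur genes passed for 24 to 72 h against 0 and 1 h. Each had an adjusted p of 0.0335, and 0 lists passed for the late comparison. The estimated version also missed a simulated list shifted by 1 log2 unit, where the noise was independent. For the sulfur list from 0 and 1 h to 24 to 72 h, the estimated correlation was 0.024, near the preset one. Its median-centred camera p before adjustment still went from 1.23e-06 to 0.0028. The lost calls therefore cannot be assigned to correlated genes alone, and low power stays open. The rank correlation, a trend over the 10 arrays from 24 to 264 h rather than the late comparison itself, gave 6 lists. Mating and reference genes were among them but had not passed camera in the late comparison (adjusted p = 0.0589 and 0.0787). Without single arrays the camera counts at the preset correlation ran from 8 to 14 and from 11 to 18.

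The difference of the ribosomal protein list between 1 h and 0 h, 4.57, was 5.86 as deposited and 2.40 after quantile normalization. As deposited, with the all-gene shift of 1.30 left in, list medians of 1 h against 0 h changed sign for fatty acid and phospholipid synthesis (0.75), hypoxic genes (0.79), seripauperin genes (0.82), peroxisomal fatty acid oxidation (0.47), glycogen and trehalose (0.79), heat shock (0.50) and iron and copper uptake (0.71), each below that shift. From 0 and 1 h to 24 to 72 h the ribosomal protein list, -0.08, was 0.34 after quantile normalization and 0.17 with equal median absolute deviations. It ran from -2.26 without 0 h to 2.11 without 1 h (0.48 without 72 h), translation factors from -1.59 to 1.08 and glycolysis from -0.93 to 1.20, because the 0 h and 1 h arrays lay far apart.

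No paired analysis was possible because each time had 1 sample and no label paired samples. Where 0 h or 1 h was left out, the lone sample was assumed to vary like the other groups. The signal over background was unknown, so the number of genes near background could not be given.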

Other observations

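Tests chosen only after the result was seen were those of the signal range (late arrays, 1 h array and 192 h array), of a failed 0 h array and of the 192 h array alone, as well as the splits of the quantile-normalized arrays and the trends of list means. The test of the 240 h array and the splits of the median-centred arrays were planned.

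The late fall of the ribosomal protein, ergosterol and glycolysis lists was weighed against the narrower signal of the late arrays. After quantile normalization, which gives all arrays the same range, the highest of the 3 list medians still lay at percentile 0.88 of matched random lists, which argues against the range as the whole cause. Without the 240 h array the smallest ratio of list medians was 0.787, which argues against that array alone. Of 35 splits of the 7 arrays, 2 called as many genes as the real 5 (highest other 142) and 4 as many lists as the real 15 (highest other 18), so chance could not be excluded in median-centred values. All splits but those 2 called 0 genes there. After quantile normalization only the real split, 1 of 35, gave as many as its 72 genes (highest other 38). The split with 142 genes was the grouping by time with 168 h moved to the earlier arrays. Both splits that called genes thus cut the 7 arrays in order of time. The 142 genes are therefore no sign that an arbitrary grouping calls as many. With 2 of 35 splits the test itself still could not exclude chance. Any change between 168 and 192 h could give such a split, and no biological explanation was tested.

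The rise of ribosomal protein transcripts from 0 to 1 h lay at percentile 100 of random lists matched on the level at 0 h, which argues against the wider signal range at 1 h as the whole cause. A failed 0 h array stays open: its best Spearman correlation across genes was 0.727, between the lowest (0.583) and the median (0.759) of the other arrays' best values. That correlation was with the 168 h array. The 0 h array had 0.718 with 120 h and 0.700 with 72 h, but 0.399 with 1 h and 0.273 with 240 h. The difference may reflect a response of the yeast to wort, but no biological explanation was tested.

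In median-centred values ergosterol genes stepped down between 168 and 192 h, while after quantile normalization their mean fell without a single step up to 240 h (2.92 at 120 h, 2.11 at 144 h, 1.86 at 168 h, 1.21 at 192 h and 0.31 at 240 h). At 264 h it was higher again, at 1.18. In median-centred values, where the step was seen, the list median changed by -1.24 from 168 to 192 h. Matched random lists had a median of -1.13, and the list lay at percentile 29.65 of them. The narrower range at 192 h therefore stays open as the cause of that step. The quantile-normalized difference from 168 to 192 h was smaller, at -0.69, and lay at percentile 0.65 of matched random lists. It argues against the range only as the whole cause of this smaller fall. The 192 h array alone is argued against, since the higher of the list means at 240 and 264 h was 0.90, below the lowest from 24 to 168 h (2.15). No biological explanation was tested.

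Over the 10 arrays from 24 to 264 h, the means of 40 lists were correlated with hours, with permutation p (the smallest they can give is 1e-05). Mating genes rose, with Pearson r = 0.904 (permutation p = 5e-05, adjusted p = 0.00180) and Spearman rho = 0.964 (permutation p = 3e-05, adjusted p = 0.00120), and r was 0.876 without the 24 and 264 h arrays and 0.890 without 240 and 264 h (264 h is the farthest from the median time, and 24 and 240 h are equally far). The mean of the mating list was below the median gene on each array from 24 h (-0.60) to 240 h (-0.12) and above it only at 264 h (0.22). The background was unknown at these levels. The list did not pass camera (adjusted p = 0.0589). In all, 1 list rose and 5 fell past the threshold for rho. For r 13 lists passed (2 upward, 11 downward), the 7 others being mitosis and cytokinesis upward and purine and pyrimidine synthesis, sulfur, vacuolar ATPase, amino acid synthesis, respiratory chain and maltose genes downward, with adjusted p for rho from 0.0759 to 0.180. After quantile normalization 9 lists passed for r (1 upward, 8 downward). Mitosis and cytokinesis (adjusted p for r = 0.0596), purine and pyrimidine synthesis (0.0589), amino acid synthesis (0.105) and reference genes (0.196) then did not. Ergosterol synthesis had r = -0.939 (permutation p = 9e-05, adjusted p = 0.00180), rho = -0.939 (permutation p = 0.00026, adjusted p = 0.00520) and r = -0.939 and -0.913 without those pairs. Translation factors had r = -0.917 (permutation p = 0.00023, adjusted p = 0.00307), rho = -0.879 (permutation p = 0.00165, adjusted p = 0.0218) and r = -0.895 and -0.885 without them. Ribosomal proteins had r = -0.856 (permutation p = 0.00074, adjusted p = 0.00740), rho = -0.867 (permutation p = 0.00218, adjusted p = 0.0218) and r = -0.852 and -0.851 without them. Glycolysis had r = -0.864 (permutation p = 0.00126, adjusted p = 0.0101), rho = -0.818 (permutation p = 0.00584, adjusted p = 0.0393) and r = -0.811 and -0.774 without them. Commonly used reference genes had r = -0.793 (permutation p = 0.00608, adjusted p = 0.0233), rho = -0.818 (permutation p = 0.00590, adjusted p = 0.0393) and r = -0.672 and -0.659 without them, and did not pass after quantile normalization (rho = -0.552, adjusted p = 0.279), where the vacuolar ATPase list passed instead (rho = -0.806, adjusted p = 0.0473). The reference list shares TDH3 with the glycolysis list. TDH3 and ACT1 had the widest median-centred ranges in the reference list (32.5- and 16.3-fold over the course), and IPP1 the next (8.92-fold). The samples follow each other in time, so the p-values are not those of independent samples.

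Genes high at 0 h and highest later at 168 h in median-centred values included HSP30 (4.37 and 5.49), HSP26 (3.72 and 5.24), SPG1 (2.44 and 4.50) and HXT6 (3.78 and 5.25). After quantile normalization the heat shock list was higher at 192 h (1.82) than at 168 h (1.47). The hexose transporter list was still highest at 168 h (1.45). The range of ACT1 over the course was 16.3-fold in median-centred values, where the median gene had 4.26-fold, and 3.89-fold after quantile normalization, where the median gene had 4.22-fold.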
